A study of Mus musculus with 12 samples.

How the data were processed

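Livers of ICR mice aged 8 weeks were profiled by RNA sequencing in 12 libraries, 3 in each of 4 groups, and each library was placed in its group by the title and description in the labels. The authors deposited 1 table of FPKM for 21004 genes, with values to the second decimal place. Per the labels, reads were aligned to mm10 with Bowtie 0.12.2. The quantifier and the annotation behind the deposited values are not given in the sources used here. The files hold no counts, so the depth per library is unknown and no interval or floor for counting error is given. The values behaved as FPKM when checked, without a common total, as the sum per library ran from 514647 to 665060.

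Gene IDs were matched to the RefSeq annotation of GRCm38, patch release 6, which has the coordinates of mm10, and 20841 IDs or 99.2% were found. Symbols that had been stored as dates were restored through the gene ID for 26 genes. Plin2 stands on 2 gene IDs.

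Genes with at least 1 FPKM in at least 3 libraries were tested, which left 10786. On log2(FPKM + 1), 1 linear model with 4 group means was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, leaving 8 residual degrees of freedom, and variances were moderated with a mean-variance trend (eBayes with trend). Each of 6 comparisons was tested two-sided, and p-values were adjusted by Benjamini-Hochberg within the comparison, with a threshold of 0.05. The comparisons were each single treatment against control, both treatments against control, both against each single treatment, and the interaction. The smallest two-sided p that an exact permutation test of 3 against 3 libraries can give is 0.1, so no such test is given for single genes. The count-based tests planned for counts were not run.

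Before the data were examined, 50 gene lists of 1107 unique members were fixed for pathways, liver zones, cell types and sample quality, of which 28 members were not in the table. Camera, a test of whether a list's genes rank higher or lower than the other genes, was run with a preset correlation of 0.01 between genes on the 41 lists with at least 5 members tested, and p-values were adjusted over these lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were run as alternatives. Lists with fewer than 5 members tested were not tested. Members past the gene test were counted over all genes and adjusted over the list alone.

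Control and busulfan libraries with the same replicate number deviated together from their group means, with correlations of 0.399, 0.157 and 0.11 for numbers 1, 2 and 3. That is a hint from the data, not from the labels, that these numbers pair the samples. The main tests did not use it, and the replicate number as a block was run as an alternative. The comparisons, tests, thresholds, lists and the rule for named genes were chosen before the data were examined. By that rule, the genes named are the 8 largest rises and 8 largest falls among genes that passed, whose groups did not overlap and whose mean in the higher group was at least 1 FPKM, leaving out symbols of predicted genes. Where fewer than 5 genes passed, the 5 with the smallest p are named. Up to 4 members of each named list, those with the smallest p, may be named too, and lists are named if they passed (at most 10 by p) or were fixed for naming whatever their result. Going beyond that rule, every list that passed is given in L.J. versus control and in busulfan plus L.J. versus L.J., where the lists past the first 10 are given without fits that leave out 1 library unless they were fixed for naming. Coordinates, group means and SD come from the same tables.

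The effects of a treatment with and without the other were compared by Pearson correlation and covariance across genes, in pairs of comparisons that share no library. The share of genes with opposite signs in 2 comparisons that share the busulfan libraries was set beside 1000 random rotations of the residuals. The same rotations gave, for every list tested, how far out its medians lay in both comparisons, each over the SD of its own rotations. The rotations left out the replicate block, and were repeated with it.

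Alternatives planned were pseudocounts of 0.1 and 0.01, no filter, a filter of at least 5 FPKM in 3 libraries, median scaling, quantile normalization, eBayes without trend and robust eBayes, the libraries of the compared groups alone, the replicate number as a block, and leaving out each library in turn. The list test followed each of these except robust eBayes. Alternatives added after seeing the data were leaving out the L.J. group, leaving out L.J. replicates 1 and 3, library weights, and leaving out the 21 Mup genes with rescaling. The tests were tried on simulated data with 10786 genes and 50 changed genes of each size. Noise was drawn independently for each gene, with 1 moderated spread per gene for all 12 libraries. It held neither the correlation between genes nor the wider spread of the L.J. group. The shares recovered and the false calls therefore do not give the error rate in the real libraries. In busulfan versus control 14% of changes of 0.5 on the log2 scale, 70% of changes of 1 and 98% of changes of 2 were recovered, with 5 false calls. In L.J. versus control these shares were 26%, 80% and 94%, with 3 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library and no value column was left out of the main tests. Mitochondrially encoded genes were not analysed here.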

Results

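Total RNA from the livers of ICR mice, an outbred strain, was sequenced at 8 weeks of age. The 12 libraries fell into 4 groups of 3: control, busulfan, L.J. at 10 mg/kg, and busulfan plus L.J. Busulfan is an alkylating agent that crosslinks DNA and depletes stem cells of the bone marrow and the germ line. The labels do not say what L.J. stands for, and it is named here as they name it. The design text of the series speaks of FMT, and neither it nor the labels say how L.J. relates to FMT, so what was given is open. The values were FPKM, fragments counted per length of transcript and per size of the library, and the depth of each library is unknown. Nothing beyond the labels states that the replicates came from separate animals, so the p-values measure the spread between these samples. Means below are FPKM ± SD over the 3 libraries of a group, log2 fold changes are fitted values with their SE where given, and positions are on mm10.

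The major urinary protein genes (Mup, abundant secreted pheromone carriers of male mouse liver) set the L.J. libraries apart. These 21 genes held 11.7% of all FPKM in control replicate 1 and 35.4% in control replicate 2, but 1.37% in L.J. replicate 1 and 0.0956% in L.J. replicate 3. In L.J. replicate 2 they held 23.9%, inside the range of the control libraries. Mup2 alone read 1646, 46570 and 84.2 FPKM in L.J. replicates 1, 2 and 3. Reads of the Mup genes are hard to assign to single members, because the genes are nearly identical. The sum of FPKM ran from 514647 in L.J. replicate 3 to 665060 in busulfan plus L.J. replicate 1. The first principal component of the 10786 genes tested held 47.9% of the variance, and Pearson correlations across genes between libraries of a group ran from 0.943 to 0.989. Both L.J. replicates that stand apart bear on every comparison with the L.J. group. Through the spread per gene that all groups share in the model, they bear on the p-values of the other comparisons too. In limma, busulfan versus control had 139 genes at an unadjusted p under 0.05, and 196 without the L.J. group.

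Busulfan versus control asked what busulfan alone changed in the liver, the adverse effect that the series set out to reverse. The interferon-stimulated genes, which restrict viral infection, had higher values with busulfan in all 34 members tested, with a median log2 fold change of 0.36 (0.58 and 0.21 without control replicates 1 and 2, and 0.22 without busulfan replicate 2). Ifit1, which binds viral RNA, read 1.67 ± 0.265 in control and 3.42 ± 1.35 with busulfan, and the chemokine Cxcl9 3.61 ± 1.22 and 7.27 ± 1.79. The PPARA targets and fatty acid oxidation genes, which burn fat in the liver, lay slightly lower in 27 of 33 members, with a median of -0.12 (-0.01 without control replicate 1, and -0.21 and -0.06 without busulfan replicates 1 and 3). Cyp4a32, a fatty acid hydroxylase, read 46.5 ± 24.8 and 21.9 ± 7.15. The MHC and antigen presentation genes lay higher in 18 of 19 members, with a median of 0.23 (0.41 and -0.03 without control replicates 1 and 2).

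No gene passed the test, and the 5 genes with the smallest p are given as values that did not pass, each at an adjusted p of 1 in limma. Arl4d, a small GTPase (gene ID 80981, chromosome 11, 101665541 to 101667832), read 17.7 ± 1.69 in control and 31.3 ± 5.40 with busulfan. Irf2bp2, a transcriptional corepressor (gene ID 270110, chromosome 8, 126588296 to 126593986), read 8.84 ± 1.42 and 17.4 ± 2.09. Slc25a25, a mitochondrial carrier of ATP and phosphate (gene ID 227731, chromosome 2, 32414487 to 32451470), read 30.1 ± 5.18 and 63.0 ± 15.7. Arrdc3, an arrestin-domain adaptor (gene ID 105171, chromosome 13, 80883384 to 80896042), read 39.0 ± 14.5 and 14.4 ± 0.659. Gstp3, a glutathione S-transferase of the pi class (gene ID 225884, chromosome 19, 4057470 to 4059605), read 399 ± 306 and 30.2 ± 10.2, and the control libraries were 46.7, 550 and 599. Without control replicate 1, Gstp3 was the 1 gene past the threshold, with a log2 fold change of -4.25 and an adjusted p of 0.00153, in a range of 0.00153 to 1 over the alternatives. Whether reads were shared between genes of the pi class was not tested.

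Lists tied to DNA lesions, proliferation, fibrosis and bile acids did not pass. The p53 target genes, which a DNA lesion switches on, had a median of 0.01 (adjusted p = 0.494), and Cdkn1a, which halts the cell cycle, read 12.7 ± 1.81 and 18.0 ± 7.48. The medians were 0.02 for DNA repair (adjusted p = 0.741) and -0.06 for cell cycle and proliferation, of which 6 members were tested (adjusted p = 0.383). Fibrosis and extracellular matrix genes had a median of -0.06 (adjusted p = 0.0558) and bile acid synthesis and transport genes one of -0.03 (adjusted p = 0.117). Male-biased liver genes (median 0.06) and female-biased liver genes (median -0.17) did not pass either, with adjusted p-values of 0.869 and 0.112. Of the other cell types a piece of liver holds, Kupffer cell and macrophage markers had a median of 0.26 (adjusted p = 0.0782, and adjusted p = 0.972 with an estimated correlation), but passed upward in 6 of 19 alternatives. Their adjusted p ran from 0.000315 with library weights to 0.679 without control replicate 2, and was 0.00429 and 0.00633 without control replicate 1 and busulfan replicate 3. The median was 0.55, 0.04, 0.17 and 0.44 without control replicates 1 and 2 and busulfan replicates 2 and 3. Neutrophil and monocyte markers had a median of 0.08 (adjusted p = 0.869). Sinusoidal endothelial markers had a median of 0.17 (adjusted p = 0.101), but passed upward in 6 of 19 alternatives, in a range of 0.00280 without busulfan replicate 2 to 0.828 without busulfan replicate 1. Cholangiocyte markers had a median of 0.24 (adjusted p = 0.101), stellate cell and fibroblast markers one of -0.01 (adjusted p = 0.321) and adipocyte markers one of 0.09 (adjusted p = 0.953).

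Limma found 0 of 10786 genes past an adjusted p of 0.05, with 139 at an unadjusted p under 0.05. These were 1.29% of the genes tested, below the share of 0.05 that no effect at all would give. The values of the groups did not overlap in 639 genes, 5.92% of those tested, where chance gives 10%. Camera with a preset correlation placed 7 of 41 lists past the threshold. With an estimated correlation 0 lists passed in any of the 6 comparisons. The interferon-stimulated genes passed at 8.33e-14, against an adjusted p of 0.972 with an estimated correlation, and the largest adjusted p without 1 library was 1.17e-05. None of the members of any of the 7 lists rose or fell over all genes, and 0 did so adjusted over the list alone. The PPARA targets and fatty acid oxidation genes passed at 2.36e-06 (adjusted p = 0.972 with an estimated correlation) and at 0.0620 without control replicate 1. Cytosolic ribosomal proteins, with a median of -0.05 (from -0.17 without control replicate 2 to 0.11 without control replicate 1) and 35 of 42 members lower, passed at 0.00122 (adjusted p = 0.972 with an estimated correlation), but gave 0.956 without control replicate 1 and 0.339 without busulfan replicate 2. Erythroid cell markers, with a median of -0.34 over 9 members (-0.06 and -0.22 without control replicates 1 and 2, and -0.10 without busulfan replicate 2), passed at 0.00167 (adjusted p = 0.804 with an estimated correlation), but gave 0.0620 without control replicate 1 and 0.0654 without busulfan replicate 2. Control replicate 1 held 1407 FPKM of the globin Hba-a1, where the control mean was 669 ± 640 and the busulfan mean 248 ± 78.2. Nuclear-encoded oxidative phosphorylation genes, with a median of -0.04 (from -0.11 without control replicate 2 to 0.03 without control replicate 1), passed at 0.0120 (adjusted p = 0.972 with an estimated correlation). Without control replicate 1, control replicate 3, busulfan replicate 2 or busulfan replicate 3 that p was 0.355, 0.0542, 0.493 or 0.117. The MHC and antigen presentation genes passed at 0.0363 (adjusted p = 0.972 with an estimated correlation), but gave 0.760, 0.229, 0.136 and 0.194 without control replicates 2 and 3 and busulfan replicates 1 and 3. Heat shock proteins, with a median of 0.18 (0.09 without control replicate 1 and 0.08 without busulfan replicate 2) and 16 of 17 members higher, passed at 0.0380 (adjusted p = 0.972 with an estimated correlation), but gave 0.963 without control replicate 1 and 0.601 without busulfan replicate 2.

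Busulfan plus L.J. versus busulfan asked what L.J. changed in animals given busulfan. The interferon-stimulated genes lay lower with L.J. in 33 of 34 members, with a median of -0.43 (-0.26 without busulfan plus L.J. replicate 1). Usp18, which damps interferon signalling, read 3.36 ± 1.07 with busulfan and 1.57 ± 0.663 with both, and the proapoptotic Xaf1 14.0 ± 4.20 and 7.53 ± 3.65. The cholesterol biosynthesis genes lay higher in 25 of 25 members, with a median of 0.41 (0.62 and 0.27 without busulfan replicates 2 and 3). Mvd, an enzyme of the mevalonate pathway, read 8.13 ± 2.79 and 14.8 ± 3.38, and Cyp51, which demethylates lanosterol, 34.0 ± 12.3 and 58.5 ± 19.5. The glucocorticoid and fasting response genes had a median of -0.30, but one of -0.14 without busulfan replicate 2 and of 0.01 without busulfan plus L.J. replicate 1. Among them Pck1, the entry enzyme of gluconeogenesis, read 658 ± 134 and 229 ± 13.8.

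No gene passed the test, and the 5 genes with the smallest p are given as values that did not pass. Angptl4, a secreted inhibitor of lipoprotein lipase that fasting induces (gene ID 57875, chromosome 17, 33774900 to 33781575), read 42.3 ± 15.4 with busulfan and 10.7 ± 1.28 with both. Its log2 fold change was -1.83 with an SE of 0.27, and its adjusted p in limma was 0.207. Slc34a2, a sodium and phosphate cotransporter (gene ID 20531, chromosome 5, 53049353 to 53071664), read 0.833 ± 0.0737 and 3.92 ± 1.33, with an adjusted p of 0.207. Fam47e (gene ID 384198, chromosome 5, 92554960 to 92591285) read 4.63 ± 0.623 and 10.9 ± 2.11, with an adjusted p of 0.207. Riok2, a kinase of ribosome maturation (gene ID 67045, chromosome 17, 17374332 to 17394899), read 5.28 ± 0.265 and 8.89 ± 1.02, with an adjusted p of 0.262. Ip6k2, an inositol phosphate kinase (gene ID 76500, chromosome 9, 108783764 to 108806333), read 23.4 ± 3.15 and 11.4 ± 1.21, with an adjusted p of 0.481.

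Members of the lists that moved did not all follow their list. In the circadian clock and clock output list, with a median of 0.26 (0.48, 0.17 and 0.10 without busulfan plus L.J. replicates 1, 2 and 3) and a mean of 0.04, the period gene Per2 read 1.71 ± 0.306 and 3.84 ± 0.757. Nr1d1 and Nr1d2 lay lower, with 26.3 ± 20.5 and 3.46 ± 0.198 for Nr1d1 and 8.20 ± 3.44 and 2.38 ± 0.312 for Nr1d2, and neither passed. In the unfolded protein response and ER stress list, with a median of 0.19 (0.10 without busulfan plus L.J. replicate 3), the chaperone Calr read 633 ± 88.3 and 872 ± 138. Herpud1, of ER-associated degradation, read 147 ± 30.9 and 80.7 ± 21.5. The amino acid catabolism and urea cycle list had a median of -0.10 (from -0.25 without busulfan plus L.J. replicate 2 to 0.01 without busulfan replicate 1), with 26 of 34 members lower. The p53 target genes (median 0.01, adjusted p = 0.817), cell cycle genes (median 0.06, adjusted p = 0.694), fibrosis genes (median -0.00, adjusted p = 0.817) and bile acid genes (median -0.11, adjusted p = 0.285) did not pass. Neither did the male-biased (median -0.00, adjusted p = 0.957) nor the female-biased liver genes (median 0.06, adjusted p = 0.957). Kupffer cell and macrophage markers had a median of 0.16 (adjusted p = 0.512) and neutrophil and monocyte markers one of 0.16 (adjusted p = 0.624). Erythroid markers had a median of 0.53 against a mean of -0.06 (adjusted p = 0.539), and adipocyte markers had a median of 0.06 (adjusted p = 0.762). Endothelial (median -0.06, adjusted p = 0.624) and stellate cell markers (median -0.04, adjusted p = 0.694) did not pass. Among cholangiocyte markers (median -0.04, adjusted p = 0.527), Sox9, a biliary transcription factor, rose adjusted over the list alone, from 2.12 ± 0.550 to 4.77 ± 1.33. The pancreatic amylase Amy2a5 was listed at 0 in every busulfan library and read 7.75, 120 and 0.24 in busulfan plus L.J. replicates 1, 2 and 3.

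Limma found 0 genes past the threshold and 402 at an unadjusted p under 0.05, which is 3.73% and again below a share of 0.05. In 1077 genes, 9.99%, the groups did not overlap, where chance gives 10%. Camera placed 7 lists past the threshold, each with an adjusted p of 0.995 with an estimated correlation. The interferon-stimulated genes passed at 5.10e-15, cholesterol biosynthesis at 8.00e-07, MHC and antigen presentation at 0.000377 (median -0.23, or -0.04 and -0.36 without busulfan plus L.J. replicates 1 and 3) and the glucocorticoid and fasting response at 0.00135 (median -0.30). No member of the 7 lists rose or fell over all genes. Adjusted over the list alone, 4 fell in the glucocorticoid and fasting response and 0 changed in the other 6 lists. The unfolded protein response and ER stress list passed at 0.0258, but gave 0.262, 0.103 and 0.144 without busulfan replicate 1 and busulfan plus L.J. replicates 1 and 3. The amino acid catabolism and urea cycle list passed at 0.0258, but gave 0.550 without busulfan replicate 1, and 0.981 with the test turned upward without busulfan plus L.J. replicate 3. The circadian clock and clock output list passed at 0.0369, but gave 0.0980, 0.117 and 0.131 without busulfan replicates 1 and 2 and busulfan plus L.J. replicate 3.

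**Figure D1:**
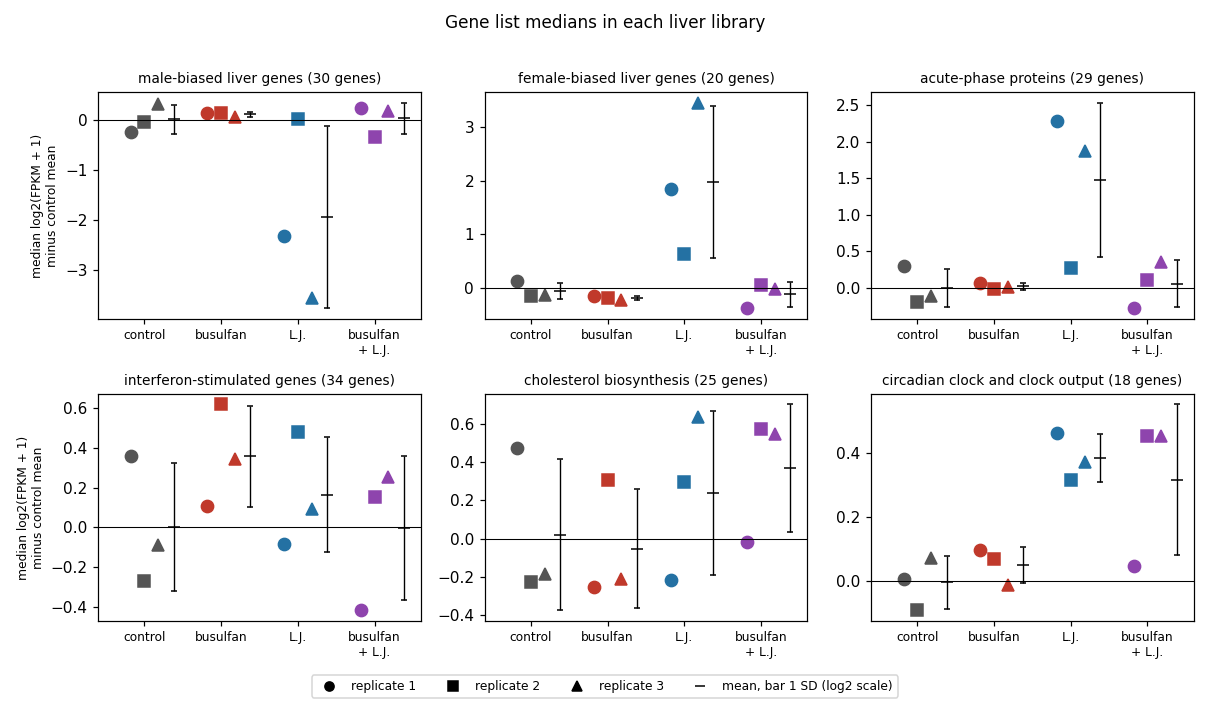
Each point is 1 library's median over a list of log2(FPKM + 1) minus the mean of the control libraries, for 6 lists in the 4 groups, with the mean and a bar of 1 SD beside the points of each group. In L.J. replicates 1 and 3 the male-biased liver genes lie at -2.31 and -3.56 and the acute-phase proteins at 2.28 and 1.88, while L.J. replicate 2 lies at 0.02 and 0.27.

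L.J. versus control asked what L.J. alone changed. The acute-phase proteins, which the liver secretes in inflammation, were higher in 28 of 29 members, with a median of 1.66. Serum amyloid A, an apolipoprotein of the acute phase, rose from 62.1 ± 15.6 to 2984 ± 2189 for Saa1 and from 39.9 ± 21.4 to 2765 ± 2127 for Saa2. Female-biased liver genes were higher in 18 of 20 members, with a median of 2.01. The sulfotransferase Sult3a1 rose from 0.953 ± 1.45 to 339 ± 487. Male-biased liver genes were lower in 28 of 30 members, with a median of -1.99, and Angptl4 fell from 43.7 ± 14.2 to 11.5 ± 2.21.

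These shifts were uneven between the 3 L.J. libraries. The medians of the male-biased genes were -2.31, 0.02 and -3.56 in replicates 1, 2 and 3, those of the female-biased genes 1.85, 0.64 and 3.45, and those of the acute-phase proteins 2.28, 0.27 and 1.88. Saa1 read 4454, 468 and 4030 and Sult3a1 60.2, 56.0 and 901. Without L.J. replicate 3 the male-biased median was -1.13 and the female-biased one 0.96, without L.J. replicate 2 the male-biased one was -3.04, and without L.J. replicate 1 the acute-phase one was 1.07. The Mup genes are part of the male-biased list, which without them kept 22 of 30 members and a median of -1.41.

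**Figure D2:**
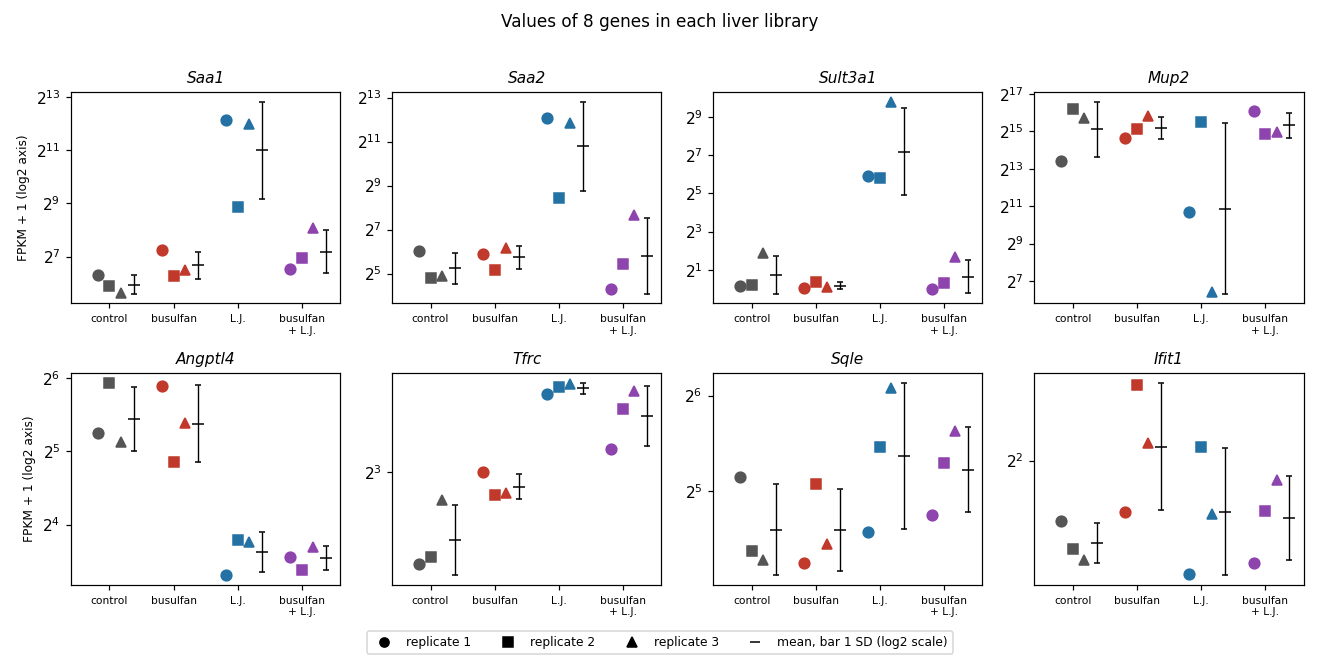
FPKM + 1 on a log2 axis of 8 genes in the 12 libraries, 1 point per library, with the mean and a bar of 1 SD on the log2 scale beside each group. Angptl4 lies lower and Tfrc higher in both groups given L.J., and Saa1, Saa2 and Mup2 in L.J. replicate 2 lie nearer to the control libraries than in L.J. replicates 1 and 3.

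In limma, 27 genes passed, of which 21 rose and 6 fell, and 14 of them met the naming rule fixed beforehand, not all of which are given here. The largest log2 fold change was that of Sult3a1 (gene ID 57430, chromosome 10, 33851020 to 33879475), at 6.47 with an SE of 0.89 and an adjusted p of 0.0160. Saa2 (gene ID 20209, chromosome 7, 46751833 to 46754313) and Saa1 (gene ID 20208, chromosome 7, 46740497 to 46743181) rose by 5.54 and 5.04, with adjusted p-values of 0.0428 and 0.0172. Both are near-identical neighbours, so reads may be shared. Jchain, the joining chain of secreted antibodies, rose from 0.660 ± 0.139 to 18.3 ± 13.0, Sik1, a kinase that restrains gluconeogenesis, from 2.08 ± 0.12 to 11.4 ± 4.81, the nuclear envelope protein Syne4 from 1.22 ± 0.645 to 7.76 ± 3.12, and the pseudokinase Nrbp2 from 12.6 ± 2.38 to 40.7 ± 16.2. The smallest adjusted p, 0.00886, was that of Prkd3, a protein kinase D (gene ID 75292, chromosome 17, 78949405 to 79020816), which fell from 26.8 ± 2.31 to 11.4 ± 1.62, with a log2 fold change of -1.17 and an SE of 0.12. Angptl4 fell by 1.81 on the log2 scale (adjusted p = 0.0183). Etnppl, which degrades phosphoethanolamine (gene ID 71760, chromosome 3, 130617448 to 130635750), fell from 38.4 ± 5.44 to 15.8 ± 2.07, and Ndrg1, a stress-responsive gene (gene ID 17988, chromosome 15, 66929318 to 66969641), from 12.2 ± 1.43 to 5.29 ± 0.600. The protease inhibitor Serpina5 fell from 2.53 ± 0.290 to 0.717 ± 0.339 and the corepressor Tle1 from 12.03 ± 1.06 to 7.65 ± 0.565.

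The metabolic and immune lists moved as well. The bile acid synthesis and transport genes were lower, with a median of -0.15, which was -0.04 and -0.26 without control replicates 1 and 2 and -0.04 without L.J. replicate 2 (adjusted p = 5.31e-05, and adjusted p = 0.280 with an estimated correlation), and adjusted over the list alone 4 rose and 6 fell. Cyp8b1, which sets the share of cholic acid, read 171 ± 40.2 and 52.4 ± 36.1. The PPARA targets and fatty acid oxidation genes had a median of -0.24, and -0.12 without control replicate 1 (adjusted p = 5.09e-10, and adjusted p = 0.366 with an estimated correlation), with 1 member, Angptl4, past the test over all genes and 1 up and 4 down adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes were lower in 34 of 37 members, with a median of -0.19, and -0.10 without control replicate 1 (adjusted p = 6.27e-13, and adjusted p = 0.366 with an estimated correlation), and 0 changed adjusted over the list alone. Phase II conjugation enzymes had a median of -0.30, and -0.16 without control replicate 3 and -0.10 without L.J. replicate 3 (adjusted p = 1.86e-06, and adjusted p = 0.280 with an estimated correlation), with 1 up over all genes and 3 up and 6 down adjusted over the list alone. Inflammatory cytokines and chemokines were higher in 18 of 18 members, with a median of 0.61, and 0.96 without L.J. replicate 2 (adjusted p = 0.000393, and adjusted p = 0.701 with an estimated correlation), and 8 rose adjusted over the list alone. Icam1, an adhesion molecule, read 3.95 ± 0.50 and 11.2 ± 4.50. Neutrophil and monocyte markers were higher in 7 of 7 members, with a median of 0.62 (adjusted p = 0.00172, and adjusted p = 0.405 with an estimated correlation), and 5 rose adjusted over the list alone. S100a9, a calcium-binding protein of neutrophils, read 1.15 ± 0.559 and 33.6 ± 28.4, and Lcn2, an iron-sequestering protein that hepatocytes also make in the acute phase, 8.29 ± 7.54 and 796 ± 680. The NRF2 targets and glutathione genes ranked lower (adjusted p = 0.00107, and adjusted p = 0.716 with an estimated correlation) with a mean of -0.10, but their median was 0.02 (from -0.11 without control replicate 2 to 0.15 without control replicate 1), and it was -0.18 with median scaling, -0.06 with quantile normalization and -0.10 with the Mup genes left out.

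The remaining 9 lists past the threshold lost the call with an estimated correlation too. The unfolded protein response list had a median of 0.51 (adjusted p = 0.00493, and adjusted p = 0.677 with an estimated correlation), and 10 rose adjusted over the list alone. The corresponding medians and p-values were 0.70 for metallothioneins and zinc transport (0.0305 and 0.423), 0.44 for MHC and antigen presentation (0.0305 and 0.772) and 0.37 for cytosolic ribosomal proteins (0.0404 and 0.851). Kupffer cell and macrophage markers were higher in 17 of 17 members, with a median of 0.75, and 0.43 without L.J. replicate 1 (adjusted p = 0.0326, and adjusted p = 0.850 with an estimated correlation), but gave 0.146, 0.109 and 0.260 without control replicates 2 and 3 and L.J. replicate 1. Erythroid cell markers had a median of -0.01, from -0.67 without control replicate 2 to 0.39 without control replicate 1 (adjusted p = 0.0283, and adjusted p = 0.405 with an estimated correlation), but gave 0.341, 0.153 and 0.0749 without control replicate 1 and L.J. replicates 1 and 3. In 3 lists ranked lower the median was above 0, at 0.02 for heat shock proteins (mean -0.13, adjusted p = 0.0305, and 0.749 with an estimated correlation), 0.06 for drug-metabolising cytochrome P450 enzymes (mean 0.41, adjusted p = 0.0408, and 0.675) and 0.08 for pericentral hepatocyte genes (mean 0.12, adjusted p = 0.0408, and 0.749). The p53 target genes (median 0.20, adjusted p = 0.528) did not pass, though 4 members rose adjusted over the list alone, among them Cdkn1a at 12.7 ± 1.81 and 35.9 ± 14.5. Cell cycle (median 0.13, adjusted p = 0.746), fibrosis (median 0.08, adjusted p = 0.148), endothelial (median 0.16, adjusted p = 0.264), stellate cell (median 0.11, adjusted p = 0.126), cholangiocyte (median 0.46, adjusted p = 0.207) and adipocyte lists (median -0.06, adjusted p = 0.0592) did not pass, though the adipocyte list passed downward in 5 of 17 alternatives, in a range of 0.0108 to 0.852.

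Camera called 19 lists, of which 9 ranked higher and 10 lower. The balance turned with the scaling, to 11 and 6 with median scaling, 14 and 4 with quantile normalization and 11 and 6 with the Mup genes left out. The male-biased genes passed at 3.48e-24 (adjusted p = 0.337 with an estimated correlation), with 0 past the test over all genes and 1 up and 16 down adjusted over the list alone. The acute-phase proteins passed at 1.16e-11 (adjusted p = 0.423 with an estimated correlation), with 2 up over all genes and 27 up adjusted over the list alone. The female-biased genes passed at 1.86e-06 (adjusted p = 0.423 with an estimated correlation), with 2 up over all genes and 14 up adjusted over the list alone. At an unadjusted p under 0.05 limma gave 2505 genes, and 2242 genes, 20.8%, did not overlap where chance gives 10%. The median log2 fold change of all genes was 0.17 as deposited and 0.01 after median scaling, so a list median is to be read against 0.17. After median scaling 47 genes rose and 52 fell. The count of 27 became 71, 5 and 1 without control replicates 1, 2 and 3, and 20, 1796 and 3 without L.J. replicates 1, 2 and 3. With only the groups compared, where the spread comes from the control and L.J. libraries alone, all 14 genes that met the naming rule missed the threshold. Their adjusted p-values in limma then ran from 0.177 to 0.259. Each of the 14 genes also missed the threshold in at least 1 fit without a single library. Prkd3 did so without control replicate 3 (adjusted p = 0.0526), and Sult3a1 without control replicates 2 and 3 (adjusted p = 0.0619 and 0.0670). For the other 12 of these genes the libraries were among control replicates 1, 2 and 3 and L.J. replicates 1 and 3, with adjusted p-values from 0.0515 to 0.201. In limma Sult3a1 also missed the threshold with no filter (adjusted p = 0.0515), a pseudocount of 0.01 (adjusted p = 0.056) and robust eBayes (adjusted p = 0.0509). Saa1, Saa2, Angptl4, Jchain, Nrbp2, Tle1, Serpina5 and Syne4 missed it with no filter too, and Saa2, Jchain, Nrbp2 and Tle1 with robust eBayes.

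Busulfan plus L.J. versus control asked what still differed from control after both treatments. The cholesterol biosynthesis genes were higher in 24 of 25 members, with a median of 0.38 (0.59, 0.21 and 0.235 without control replicates 1, 2 and 3, and 0.58 without busulfan plus L.J. replicate 1), and Sqle, the squalene epoxidase, read 24.2 in control and 37.5 with both. The PPARA targets and fatty acid oxidation genes lay lower in 21 of 33 members, with a median of -0.06 that turned to 0.03 without control replicate 1 and 0.02 without busulfan plus L.J. replicate 1, and was -0.16 without control replicate 2. Adjusted over the list alone 3 of them fell, namely Angptl4, from 43.7 ± 14.2 to 10.7 ± 1.28, Cyp4a32, from 46.5 ± 24.8 to 12.5 ± 1.09, and Cpt1a, the gatekeeper of mitochondrial fatty acid oxidation, from 54.7 to 36.8. The transferrin receptor Tfrc, which takes up iron (gene ID 22042, chromosome 16, 32608896 to 32632794), read 4.48 ± 1.15 and 10.1 ± 1.82. The interferon-stimulated genes had a median of -0.00 (adjusted p = 0.168) and the bile acid synthesis and transport genes one of -0.23 (-0.07 without control replicate 1 and -0.05 without busulfan plus L.J. replicate 1), with 15 of 24 members lower.

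Limma found 0 genes past the threshold and 748 at an unadjusted p under 0.05, and 1274 genes, 11.8%, did not overlap where chance gives 10%. The smallest adjusted p, 0.0785, was shared by Slc34a2, with a log2 fold change of 1.61, and Angptl4, with one of -1.89. The others named as not passing were 4833420G17Rik (chromosome 13, 119462015 to 119486120) at -0.75 (adjusted p = 0.0835), Tfrc at 1.02 (adjusted p = 0.0891) and Sik1 at 1.5 (adjusted p = 0.112). Without control replicate 1 the count was 5, without busulfan plus L.J. replicate 2 it was 1, and without the L.J. group, a choice made after seeing the data, it was 3. Camera placed 3 lists past the threshold, each with an adjusted p of 0.951 with an estimated correlation and no member past the test over all genes. PPARA targets and fatty acid oxidation passed at 0.00234, but gave 0.0571 with quantile normalization and 0.0848 with library weights, an alternative added after seeing the data. Cholesterol biosynthesis passed at 0.00915, with 0 members adjusted over the list alone, but gave 0.107 and 0.152 without control replicates 2 and 3. Bile acid synthesis and transport passed at 0.0490, with 0 members adjusted over the list alone, but gave 0.107 without control replicate 2 and 0.329 without busulfan plus L.J. replicate 3. The p53 target genes (median -0.01, adjusted p = 0.783), cell cycle genes (median 0.00, adjusted p = 0.929), fibrosis genes (median -0.07, adjusted p = 0.115), male-biased genes (median 0.07, adjusted p = 0.782) and female-biased genes (median -0.07, adjusted p = 0.319) did not pass. Neither did the markers of Kupffer cells (median 0.40, adjusted p = 0.0521), neutrophils (median 0.27, adjusted p = 0.383), erythroid cells (median -0.25, adjusted p = 0.303), cholangiocytes (median 0.29, adjusted p = 0.102), endothelium (median 0.10, adjusted p = 0.708), stellate cells (median -0.04, adjusted p = 0.204) or adipocytes (median 0.11, adjusted p = 0.764). The Kupffer cell and macrophage markers, though, passed upward in 10 of 19 alternatives, with an adjusted p from 4.27e-05 with library weights to 0.329 without busulfan plus L.J. replicate 3, and 0.951 with an estimated correlation. They passed at 0.00111 and 0.000672 without control replicate 1 and busulfan plus L.J. replicate 1, where the median was 0.76 and 0.71, and the median was 0.21 and 0.20 without control replicate 2 and busulfan plus L.J. replicate 3.

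Busulfan plus L.J. versus L.J. asked what busulfan changed in animals given L.J., and it leaned on the same uneven L.J. libraries. Ndrg1 rose from 5.29 ± 0.600 with L.J. to 12.9 ± 2.18 with both, a level beside the 12.2 ± 1.43 of control. Sult3a1 fell from 339 ± 487 to 0.787 ± 1.18, and B3galt1, a galactosyltransferase of glycolipids (gene ID 26877, chromosome 2, 67565689 to 68122882), fell from 12.9 to 5.76. The male-biased liver genes were higher in 28 of 30 members, with a median of 2.03, the female-biased lower in 19 of 20, with a median of -1.89, and the acute-phase proteins lower in 28 of 29, with a median of -1.31. Without L.J. replicate 3 the male-biased and female-biased medians were 1.32 and -1.05, and without L.J. replicate 2 the acute-phase one was -2.10. The phosphoethanolamine lyase Etnppl, at 15.8 ± 2.07 and 35.2 ± 5.67, did not pass (adjusted p = 0.0547), nor did Slc34a2, at 0.757 ± 0.463 and 3.92 ± 1.33 (adjusted p = 0.0563).

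Limma found 3 genes past the threshold, with 1471 at an unadjusted p under 0.05, and 1402 genes, 13.0%, did not overlap where chance gives 10%. The median log2 fold change of all genes was -0.127, so a list median is to be read against it. The log2 fold change was 1.14 for Ndrg1 (SE 0.14, adjusted p = 0.0338) and -6.55 for Sult3a1 (SE 0.89, adjusted p = 0.0380). For B3galt1 the SE was 0.13 and the adjusted p 0.0338. The count was 1163 without L.J. replicate 2, 0 without L.J. replicate 1, 1 without busulfan plus L.J. replicate 1, 2 without busulfan plus L.J. replicate 2, of which 0 were among the 3, and 0 without busulfan plus L.J. replicate 3. The call of Ndrg1 was also lost without L.J. replicate 3 (adjusted p = 0.0675). With only the groups compared 2 genes passed and 0 of the 3 did, at 0.134 for Ndrg1 and B3galt1 and 0.181 for Sult3a1. The call of Sult3a1 was lost too with pseudocounts of 0.1 (adjusted p = 0.0958) and 0.01 (adjusted p = 0.166), with no filter (adjusted p = 0.0743) and with robust eBayes (adjusted p = 0.144). Sult3a1 and B3galt1 also lost the call under other scalings. Their adjusted p-values were 0.0971 and 0.119 with median scaling, 0.0864 and 0.103 with quantile normalization and 0.079 and 0.103 with the Mup genes left out. Ndrg1 kept its call in these. Over all alternatives the adjusted p ran from 0.000190 to 0.914 for Ndrg1, 0.000485 to 0.420 for B3galt1 and 0.000190 to 0.396 for Sult3a1. Camera called 17 lists, 9 upward and 8 downward, and 7 and 9 with median scaling, 6 and 12 with quantile normalization and 8 and 8 with the Mup genes left out. The male-biased genes passed at 3.24e-28 (adjusted p = 0.359 with an estimated correlation), with 22 up and 1 down adjusted over the list alone. The acute-phase proteins passed at 1.00e-15 and the female-biased genes at 9.80e-11, each with an adjusted p of 0.451 with an estimated correlation, and 26 and 16 members fell adjusted over the list alone. Over all genes Sult3a1 was the 1 member of any of these lists past the test. The oxidative phosphorylation genes passed at 2.00e-09 with a median of 0.13, and 0.08 without busulfan plus L.J. replicate 2 (adjusted p = 0.451 with an estimated correlation). Phase II conjugation enzymes passed at 5.87e-06 with a median of 0.22, and 0.44 without L.J. replicate 2 (adjusted p = 0.359 with an estimated correlation), and 9 rose and 5 fell adjusted over the list alone. The NRF2 targets and glutathione genes passed upward at 1.32e-05 with a median of 0.10 (from 0.05 without L.J. replicate 3 to 0.24 without busulfan plus L.J. replicate 1) and the heat shock proteins at 6.87e-05 with a median of 0.19 (adjusted p = 0.560 with an estimated correlation for both). Heat shock proteins gave 0.339 and a median of 0.01 without L.J. replicate 1, and a median of 0.33 without L.J. replicate 2. Cytosolic ribosomal proteins passed downward at 4.54e-05 with a median of -0.40 and 41 of 42 members lower (adjusted p = 0.696 with an estimated correlation). The MHC and antigen presentation genes passed downward at 8.00e-05 with a median of -0.62 (adjusted p = 0.577 with an estimated correlation), and 7 fell adjusted over the list alone. The glucocorticoid and fasting response passed downward at 8.11e-05 with a median of -0.77, and -0.40 and -1.50 without L.J. replicates 1 and 2 (adjusted p = 0.495 with an estimated correlation), and 1 rose and 8 fell adjusted over the list alone.

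The other 7 lists passed at adjusted p-values from 0.000101 to 0.0237, and none kept the call with an estimated correlation. Inflammatory cytokines and chemokines (median -0.65, adjusted p = 0.585 with an estimated correlation), neutrophil and monocyte markers (median -0.41, or -0.27 without L.J. replicate 3, adjusted p = 0.451 likewise) and the unfolded protein response genes (median -0.31, adjusted p = 0.696 likewise) were lower in every member. Cholesterol biosynthesis (median 0.06, adjusted p = 0.696 with an estimated correlation) and PPARA targets and fatty acid oxidation (median 0.10, adjusted p = 0.585 likewise) ranked higher. Bile acid synthesis and transport ranked higher with a median of 0.01, from -0.11 without L.J. replicate 2 to 0.08 without busulfan plus L.J. replicate 3 (adjusted p = 0.0161, and adjusted p = 0.451 with an estimated correlation), but gave 0.135 and 0.0819 without busulfan plus L.J. replicates 1 and 2. Pericentral hepatocyte genes ranked higher with a median of 0.09 and a mean of -0.02 (adjusted p = 0.560 with an estimated correlation). The p53 target genes (median -0.17, adjusted p = 0.260), cell cycle genes (median -0.11, adjusted p = 0.849), fibrosis genes (median -0.09, adjusted p = 0.928) and the markers of Kupffer cells (median -0.28, adjusted p = 0.849), erythroid cells (median -0.42, adjusted p = 0.175), endothelium (median 0.02, adjusted p = 0.0606, but past the threshold upward in 4 of 18 alternatives, in a range of 2.06e-05 to 0.634), stellate cells (median -0.06, adjusted p = 0.765), cholangiocytes (median -0.06, adjusted p = 0.651) and adipocytes (median 0.18, adjusted p = 0.0980) did not pass.

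The interaction asked whether the L.J. effect differed with busulfan, as the L.J. effect with busulfan minus the effect without it. The male-biased liver genes had a median of 1.95, the female-biased -2.02 and the acute-phase proteins -1.52. Without L.J. replicates 2 and 3 the male-biased value was 3.04 and 1.14, and without L.J. replicate 3 the female-biased one was -0.86. With busulfan the male-biased median of the L.J. effect was -0.00, and without busulfan it was -1.99. The growth hormone feedback gene Socs2 had the values 8.86 ± 3.36 in control, 11.1 ± 2.98 with busulfan, 30.8 ± 15.5 with L.J. and 5.14 ± 2.48 with both, and did not pass. Interferon-stimulated genes had a median of -0.65 and those of the glucocorticoid and fasting response one of -1.09.

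Limma found 0 genes past the threshold, with 705 at an unadjusted p under 0.05. The median log2 value of all genes was -0.168, so a list median is to be read against it. The smallest adjusted p, 0.324, was that of Ndrg1 at a log2 value of 1.31, and the other genes named as not passing were B3galt1 at -1.04, Zfp868 at -1.89, Socs2 at -2.66 and Zfp609 at -0.76, each with an adjusted p of 0.709. Without L.J. replicate 2 the count was 295. Camera called 17 lists, 10 upward and 7 downward, a balance that turned to 7 and 12 with median scaling, 4 and 15 with quantile normalization and 8 and 10 with the Mup genes left out. The adjusted p-values of the 17 ran from 0.241 to 0.812 with an estimated correlation. The male-biased genes passed at 8.10e-26 (adjusted p = 0.241 with an estimated correlation). Interferon-stimulated genes gave 0.395 without L.J. replicate 2, cholesterol biosynthesis 0.172 and 0.203 without control replicate 1 and L.J. replicate 1, and erythroid cell markers 0.0914 without busulfan plus L.J. replicate 1. The NRF2 targets and glutathione genes ranked upward with a median of -0.04 and a mean of 0.12, and the pericentral hepatocyte genes upward with a median of -0.01 and a mean of -0.11. Not past the threshold were the p53 target genes (median -0.12, adjusted p = 0.650), cell cycle genes (median -0.07, adjusted p = 0.393), fibrosis genes (median -0.02, adjusted p = 0.229) and the markers of Kupffer cells (median -0.53, adjusted p = 0.201, but past the threshold downward in 8 of 23 alternatives, in a range of 0.00352 to 0.790), endothelium (median -0.14, adjusted p = 0.620), stellate cells (median -0.11, adjusted p = 0.331), cholangiocytes (median -0.27, adjusted p = 0.694) and adipocytes (median 0.09, adjusted p = 0.140).

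The L.J. effects with and without busulfan share no library, and across the 10786 genes their log2 fold changes correlated with a Pearson r of 0.256 and a covariance of 0.0246, with 59.0% of genes of the same sign. The r was 0.160 and the share 50.5% without busulfan plus L.J. replicate 3, and the share was 69.9% and the covariance 0.0385 without busulfan plus L.J. replicate 1. Without L.J. replicate 2 the r was 0.170. Angptl4, at -1.81 without and -1.83 with busulfan, lay near the same value in both. The busulfan effects with and without L.J. correlated with an r of 0.145 and a covariance of 0.0109, with 45.0% of genes of the same sign, and the r was 0.03 without control replicate 1, 0.223 without control replicate 3 and 0.0949 without busulfan replicate 2. That share ran from 39.0% without control replicate 1 to 53.1% without control replicate 2 and depended on the scaling, at 53.6% with median scaling, 54.7% with quantile normalization and 52.4% with the Mup genes left out. Genes are not independent replicates, so no p is given for these 2 correlations.

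A rescue by L.J., which the title of the series names, was looked for among genes that busulfan changed. Since 0 genes passed in busulfan versus control, 0 were moved back by L.J. at the threshold. Of the 139 genes at an unadjusted p under 0.05 in limma, a choice made after seeing the data, 86 or 61.9% had the opposite sign in busulfan plus L.J. versus busulfan. The 139 are 1.29% of the genes tested, fewer than no effect would give, so they cannot be read as genes that busulfan changed. Both comparisons share the busulfan libraries, and 1000 random rotations of the residuals, with no treatment effect, gave a median of 96.4% and a 95% range of 83.5% to 100%, so the observed share was below that range. With the replicate number as a block in the rotations, since control and busulfan numbers deviate together, the share was 63.6% and the range 83.3% to 100%. The share was 80.3%, 80.0% and 85.6% without busulfan replicates 1, 2 and 3 and 50.7% with at least 5 FPKM in 3 libraries, for which no range was simulated. Across all genes the r between both comparisons was -0.216, within the simulated range of -0.786 to -0.110. Ifit1, at 3.42 ± 1.35 with busulfan and 2.06 ± 0.612 with both, is one example of the interferon-stimulated genes that lay higher with busulfan and lower when L.J. was added. In 527 of the rotations at least 1 of the 41 lists lay as far out in both comparisons, with opposite signs.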

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

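Chosen only after the results were seen were the tests of Y-linked genes, of the L.J. effect with and without busulfan, of single libraries and macrophage markers for the interferon-stimulated genes, of all lists in the rotations, of other tissues, and the setting without Mup genes.

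In 17 lists the L.J. effect differed with and without busulfan by camera's test of the interaction, each reported as an adjusted p with the median log2 value of the interaction, and none passed with an estimated correlation, where adjusted p-values ran from 0.241 to 0.812. The male-biased liver genes (8.1e-26, median 1.95), nuclear-encoded oxidative phosphorylation (2.23e-12, 0.16), PPARA targets and fatty acid oxidation (1.02e-08, 0.17), phase II conjugation enzymes (1.6e-05, 0.19), cholesterol biosynthesis (2.28e-05, 0.19), erythroid cell markers (0.00079, 0.60), bile acid synthesis and transport (0.000967, 0.12) and heat shock proteins (0.0329, 0.01) ranked higher with busulfan. The acute-phase proteins (3.97e-13, median -1.52), female-biased liver genes (3.74e-08, -2.02), MHC and antigen presentation (1.34e-06, -0.70), glucocorticoid and fasting response (5.03e-06, -1.09), interferon-stimulated genes (9.64e-06, -0.65), inflammatory cytokines and chemokines (5.65e-05, -0.75) and neutrophil and monocyte markers (0.00197, -0.49) ranked lower with busulfan. The NRF2 targets and glutathione genes (0.00034) and the pericentral hepatocyte genes (0.0329) ranked higher, with medians of -0.04 and -0.01. The median of all genes was -0.168, against which these list medians are to be read. Without 1 library the medians ran from 1.14 to 3.04 for the male-biased liver genes, from -2.79 to -0.86 for the female-biased liver genes, from 0.05 to 0.23 for nuclear-encoded oxidative phosphorylation, from 0.08 to 0.26 for PPARA targets and fatty acid oxidation, from 0.07 to 0.30 for phase II conjugation enzymes, from -0.13 to 0.40 for cholesterol biosynthesis, from -0.14 to 1.04 for erythroid cell markers and from -0.05 to 0.12 for bile acid synthesis and transport. Without L.J. replicate 2 the interferon-stimulated genes gave 0.395, without control replicate 1 and L.J. replicate 1 cholesterol biosynthesis gave 0.172 and 0.203, and without busulfan plus L.J. replicate 1 the erythroid markers gave 0.0914. Of 100 splits, the real one among them, 16 gave at least 17 lists, the real one included, with 21 the highest of the others. The other splits drew the labels at random over all groups, which also breaks the effect of each treatment alone. Chance is not excluded for the lists. The real count of genes was 0, which all 100 splits reach, with 125 the highest, so that number says nothing about chance.

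L.J. replicates 1 and 3 had low male-biased, high female-biased and high acute-phase expression, and L.J. replicate 2 was nearer to the control libraries. Against female animals under a wrong label, the mean of the 4 Y-linked genes was at least 15.9 FPKM in both libraries, where the other 10 libraries ran from 12.7 to 15.3. Against a few genes taking most of the counts as the whole cause, the acute-phase median stayed at 1.54 without the Mup genes, where its SD over 1000 rotations of the residuals was 0.414, with an adjusted p of 2.83e-14, in a range of 1.28e-19 to 0.423 over the alternatives. The male-biased list holds Mup genes, and without them 22 of its 30 members stayed, with the median going from -1.99 to -1.41. The biological reading, an L.J. effect that is alike with and without busulfan, cannot be told apart from one that busulfan prevents, because the male-biased interaction had an adjusted p of 0.241 with an estimated correlation and rested on 2 of the L.J. libraries. Differences between these animals in inflammation, feeding or handling stay open and were not tested.

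The interferon-stimulated genes lay higher with busulfan and lower when L.J. was added. Chance with shared busulfan libraries is not excluded, since in 527 of 1000 rotations at least 1 of the 41 lists lay as far out in both comparisons, with opposite signs. For this list alone 14 rotations gave both medians as far out in the observed directions, and 25 did so in either sign pattern, but the list had been picked for its small p in the same libraries, so that number excludes nothing. Each median alone lay inside its 95% range without a treatment effect, 0.36 in -0.484 to 0.484 and -0.43 in -0.476 to 0.465. With the replicate number as a block in the rotations these ranges were -0.526 to 0.551 and -0.538 to 0.549, and 635 rotations held such a list. In camera with the preset correlation no single library ended the calls, as the largest adjusted p of the list without 1 library was 1.17e-05 over both comparisons. The list missed the threshold with an estimated correlation, at adjusted p-values of 0.972 and 0.995. The small p therefore rests on the preset correlation, and it does not exclude that single libraries set the size of the shift. Macrophage content cannot be told apart, since the Kupffer cell and macrophage median from busulfan to busulfan plus L.J. was 0.162, within the rotation SD of 0.385. An interferon response that busulfan raises and L.J. lowers stays open.

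Pancreatic acinar transcripts appeared in busulfan plus L.J. replicate 2, where 28 of the 29 acinar markers in the table had their highest value. Ctrb1 read 81.8 FPKM there, Amy2a5 120, Try4 31.0, Cela2a 29.5 and Pnlip 28.7. The same 5 in busulfan plus L.J. replicate 1 read 5.73, 7.75, 2.43, 2.52 and 2.20, and in the other 10 libraries these 5 ran from 0 to 2.36. Of the 29 markers 1 had a control mean of at least 1 FPKM and 2 entered the main test. A trace of pancreas in both pieces is a candidate source that cannot be told apart from other sources of acinar transcripts, since the 8 markers of pancreatic islets in the table were listed at 0 in all 12 libraries, with 0 highest in that library. Intestinal tissue cannot be told apart, with 3 of 10 intestinal markers highest in that library. No biological explanation was tested.

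Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05, and the numbers of splits with a count as large include the real one, and a real count of 0 is reached by every split. For genes, busulfan versus control gave 0 with 1 as the highest of the other splits (10 as large), busulfan plus L.J. versus busulfan 0 with 4 (10 as large), busulfan plus L.J. versus control 0 with 0 (10 as large) and busulfan plus L.J. versus L.J. 3 with 1 (1 as large). L.J. versus control gave 27 genes, and 2 splits were as large, the higher with 931 genes, which put control replicate 1 with L.J. replicates 1 and 3 and points to a structure of the samples. For lists the real counts and the highest others were 7 and 11 for busulfan versus control (7 as large, with 10, 5 and 9 in the other splits that part all 3 pairs of the same number), 7 and 16 for busulfan plus L.J. versus busulfan (9 as large), 19 and 20 for L.J. versus control (2 as large), 3 and 14 for busulfan plus L.J. versus control (10 as large) and 17 and 26 for busulfan plus L.J. versus L.J. (4 as large).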

How the results depend on the processing

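Leaving out the L.J. group, leaving out L.J. replicates 1 and 3, library weights and leaving out the Mup genes were chosen after the results were seen. Without L.J. replicates 1 and 3 the L.J. group is 1 library, assumed to vary like the other groups (6 residual degrees of freedom), so those p-values show neither that a result holds nor that it fails. Over the alternatives that gave a value, 11360 values of named genes kept their side of the threshold, 400 newly passed and 125 no longer passed. Of values that passed in either fit 0 reversed, and a change of sign was counted as kept where neither fit passed. Only genes that passed in the main fit could lose the call, and most of the named genes had not passed there. For lists 2149 were the same, 77 newly passed, 205 no longer passed and 9 reversed. Unless a reason is given, the cause was not tested. The count-based alternatives were not run, for lack of counts. The depth is unknown, so its limit on low values could not be computed.

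Genes past the threshold in busulfan versus control were 0, and 1 with only the groups compared and with library weights. In busulfan plus L.J. versus busulfan they were 0, 1 with no filter and 70 with library weights. In L.J. versus control they were 27, 0 with only the groups compared, 11 with no filter (more genes tested), 99 with median scaling, 63 with quantile normalization, 4250 with library weights and 114 with Mup genes left out. In busulfan plus L.J. versus control they were 0, 4 with only the groups compared, 1 with no filter, 1 with median scaling, 3 without the L.J. group, 3 without L.J. replicates 1 and 3 and 729 with library weights. In busulfan plus L.J. versus L.J. they were 3, 2 with only the groups compared (0 among the 3), 2 with each pseudocount, 4 with no filter and with at least 5 FPKM in 3 libraries, 2 with robust eBayes, 1 with median scaling, 1 with quantile normalization, 0 without L.J. replicates 1 and 3, 2600 with library weights and 1 with Mup genes left out. In the interaction they were 0, 862 with library weights and 1 with Mup genes left out. The library weights ran from 0.25 for L.J. replicate 2 to 3.74 for busulfan plus L.J. replicate 2, and their estimation stopped before convergence.

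Without 1 library at a time, gene counts ran from 0 to 1, 0 to 0, 1 to 1796, 0 to 5, 0 to 1163 and 0 to 295 in the order of the comparisons, and list counts from 3 to 9, 4 to 9, 14 to 23, 4 to 9, 16 to 21 and 14 to 22. List counts moved by over 1.5 times without control replicate 1 in busulfan versus control (3 lists), without busulfan replicate 1 and busulfan plus L.J. replicate 3 in busulfan plus L.J. versus busulfan (4 each), and in busulfan plus L.J. versus control without control replicates 1 and 3 (6 each) and busulfan plus L.J. replicates 1 and 2 (9 and 8). The r of the busulfan effects ran from 0.02998 without control replicate 1 to 0.223 without control replicate 3, and was 0.0949 without busulfan replicate 2, 0.0854 without L.J. replicates 1 and 3 and 0.02997 with library weights. The r of the L.J. effects ran from 0.160 without busulfan plus L.J. replicate 3 to 0.364 without busulfan plus L.J. replicate 1, and was 0.170 without L.J. replicate 2, 0.185 without busulfan plus L.J. replicate 2 and 0.414 without L.J. replicates 1 and 3. The genes moved back ran from 0 to 0 without 1 library, which says nothing, since at most 1 gene passed in busulfan versus control in those fits.

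Lists past the threshold fell to 0 with an estimated correlation in all 6 comparisons. With fry they were 6 in L.J. versus control and 0 in the other 5 comparisons. All 6 were upward and 0 downward, and 5 of them were among the 19 lists that camera called. Lists in busulfan versus control were 7 and 11 with at least 5 FPKM in 3 libraries. Lists in busulfan plus L.J. versus control were 3, 5 with only the groups compared, 6 with no filter, 5 with at least 5 FPKM in 3 libraries and 6 with library weights. With library weights they were 6, 5, 19, 16 and 20 in the other 5 comparisons. Robust eBayes has no counterpart in camera, so lists were not tested with it, and for eBayes without trend the trend was left out of camera too. Without L.J. replicates 1 and 3 they were 11 in L.J. versus control, 10 in busulfan plus L.J. versus L.J. and 10 in the interaction.

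The test of 9 lists turned direction, given as median log2 values. In busulfan plus L.J. versus busulfan the amino acid catabolism and urea cycle list stood at -0.0784 without busulfan plus L.J. replicate 3 (adjusted p = 0.981), in a range from -0.250 without busulfan plus L.J. replicate 2 to 0.0116 without busulfan replicate 1. In busulfan plus L.J. versus control the cell cycle and proliferation list stood at 0.16 with no filter (adjusted p = 0.00501), where more low-value members are tested. Without L.J. replicates 1 and 3, which leaves 1 L.J. library, Kupffer cell and macrophage markers stood at 0.0417 (adjusted p = 0.830) and erythroid cell markers at -0.0608 (adjusted p = 0.701) in L.J. versus control. In busulfan plus L.J. versus L.J. phase II conjugation enzymes then stood at 0.0321 (adjusted p = 0.923), heat shock proteins at -0.26 (adjusted p = 0.00590) and Kupffer cell and macrophage markers at 0.36 (adjusted p = 0.00415). In the interaction the male-biased liver genes then stood at 0.00538 (adjusted p = 0.929) and phase II conjugation enzymes at -0.0738 (adjusted p = 0.886).

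Over all groups 7 of 18 pairs of libraries with the same number had a correlation of residuals over 0.1, in a range of -0.286 to 0.399. Of the 12 libraries, 4 correlated best with a library of their own number. Since 1 in 3 libraries of the other groups carries the same number, chance gives about as many. Control and L.J. libraries gave 0.384, 0.14 and -0.0681 for numbers 1, 2 and 3, and busulfan and L.J. libraries 0.283, 0.117 and 0.0524. No pair with a busulfan plus L.J. library was above 0.0442. Whether the numbers pair samples outside busulfan versus control stays open. With the replicate number as a block, 1 gene passed in busulfan plus L.J. versus L.J. and 21 in L.J. versus control, and the list counts were 7, 6, 19, 3, 17 and 18. In busulfan versus control the block changed no call, with 0 genes. In L.J. versus control Angptl4, Jchain, Nrbp2 and Tle1 were not called with it, in busulfan plus L.J. versus L.J. Ndrg1 and B3galt1, and in busulfan plus L.J. versus busulfan the circadian clock and clock output list (adjusted p = 0.0616). Of the other named genes and lists it changed no call.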

Other observations

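The average effects below, and the values of the clock genes and Gstp3, were chosen only after the data were seen.

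Averaged over animals with and without busulfan, Angptl4, the inhibitor of lipoprotein lipase, fell by 1.82 with L.J. on the log2 scale (adjusted p = 0.00349), and Slc25a47, a mitochondrial carrier of liver, fell by 1.08. The autophagy genes Gabarapl1 and Ulk1 fell by 0.67 and 0.55. The transferrin receptor Tfrc rose by 0.92 (adjusted p = 0.00889), from 4.48 ± 1.15 and 6.36 ± 0.540 FPKM in control and busulfan to 11.9 ± 0.391 and 10.1 ± 1.82 in L.J. and busulfan plus L.J., and the phosphate transporter Slc20a1 rose by 0.73. Prkd3 fell by 0.89 (adjusted p = 0.00349), while Sik1, the lipogenic regulator Mid1ip1, Trib1 and Per2 rose by 1.28, 1.05, 0.86 and 1.01.

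In that average 41 genes passed in limma, 30 up and 11 down, with 1983 at an unadjusted p under 0.05. When L.J. labels were permuted within each busulfan arm, 1 of 100 draws, the real one, gave as many, and the highest of the others was 7. So large a count was rare in these draws. Chance is not excluded, since the average was chosen after the data were seen and the draws left out the replicate numbers. Without control replicates 1, 2 and 3 the count was 77, 5 and 4, without busulfan replicates 1, 2 and 3 it was 4, 8 and 5, without L.J. replicates 1, 2 and 3 it was 30, 886 and 6, and without busulfan plus L.J. replicates 1, 2 and 3 it was 59, 5 and 7. With median scaling 51 rose and 65 fell. Single genes do not stand for their pathways here, as the iron and heme metabolism and the fatty acid and triglyceride synthesis lists had adjusted p-values of 0.964 and 0.848 in the average, and the PPARA targets and fatty acid oxidation list passed at 9.16e-06 but gave 0.581 with an estimated correlation. The average busulfan effect gave 0 genes in limma, with 710 at an unadjusted p under 0.05.

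The nuclear receptor gene Nr1d1 read 14.1, 85.6 and 73.9 FPKM in control replicates 1, 2 and 3 and 3.64, 3.25 and 3.50 in the busulfan plus L.J. libraries. The pi class transferase Gstp3 read 643 ± 40.6 FPKM with L.J., 30.2 ± 10.2 with busulfan and 27.4 ± 13.3 with both, while control replicates 1, 2 and 3 read 46.7, 550 and 599.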
